A study of Mus musculus with 20 samples.

How the data were processed

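Expression was measured by microarray in abdominal skin of 20 mice, 5 in each of 4 groups formed by diet (control chow or high fat diet) and cream (imiquimod or vehicle). Per the labels, 300 ng of Trizol-extracted RNA was converted to biotinylated DNA with the GeneChip WT PLUS kit and hybridised to Affymetrix arrays. The deposited values are log2 values that, per the submitters' processing notes, come from robust multi-array averaging (RMA) with the affy package, whose versions the notes do not give. Scan batches and whether all arrays were normalised together are not given in the sources used here. No genome build was given with the values, so no coordinates are printed.

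Of 41345 array features 23521 carried exactly 1 gene symbol, 1814 several and 16010 none. The tests used 22180 genes, each represented by the single-symbol feature with the highest mean over the 20 arrays; 1082 genes had more than 1 such feature. Of the single-symbol features 23328 matched a gene of the RefSeq table, which changed 0 symbols. No filter on dim genes was applied. Groups were taken from the labels. Replicate numbers were not treated as pairs: of 30 same-number pairs of arrays across groups 4 had a correlation of residuals above 0.1 (range -0.217 to 0.320).

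Group means were fitted with limma 3.58.1 in R 4.3.3 over all 20 arrays, with moderated statistics from eBayes, and 5 contrasts were tested: IMQ against vehicle within each diet, HFD against CD within each treatment, and the interaction. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes of a contrast. In the text a log2 change is followed by its standard error and a group mean by its standard deviation, with 5 mice per group. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

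The comparisons, their tests, the 31 gene lists, the rule for named genes and all alternatives but 1 were set before the data were examined. The lists held 662 genes: cytokines of the IL-23/IL-17 axis and the IL-36 family (24 measured), antimicrobial proteins and alarmins (24), wound keratins and serpins (19), SPRR and LCE3 genes (18), terminal differentiation and barrier (35), basal keratinocyte (9), cell cycle (34), type I interferon response (26), interferon gamma and antigen presentation (23), chemokines (18), neutrophil (18), macrophage and monocyte (19), lipid-associated macrophage (16), T and NK cell (15), Langerhans and dendritic cell (16), mast cell (14), B and plasma cell (13), adipocyte (25), fatty acid and triglyceride synthesis (21), cholesterol synthesis (17), fatty acid oxidation and PPAR targets (20), sebaceous gland (19), hair shaft and inner root sheath (33), hair follicle bulge (12), melanocyte (11), fibroblast and matrix (23), endothelial (22), skeletal muscle (23), mammary epithelium (15), red blood cell (2), and immediate-early with heat shock genes (19). List members without a feature of exactly 1 symbol were not analysed here. Each list was tested with fry in limma, adjusted over the 31 lists of a contrast. Its p tests whether the genes of a list move on balance one way, and it compares them neither with other genes nor with other lists. The competitive test camera was run as an alternative with a preset correlation of 0.01 and with the estimated correlation of each list. An adjusted p given with an estimated correlation is from camera. It asks whether a list moved more than other genes, so it does not answer the same question as fry.

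Named genes were, per comparison of 2 groups, the 8 largest rises and 8 largest falls among called genes with non-overlapping groups, leaving out predicted, small RNA and receptor-family names, or the 5 smallest p where none passed. Up to 4 called members of each list with the largest changes were added, of which the text leaves some out for length, and 15 genes set in advance were followed in every comparison. For the interaction the 10 largest terms in each direction were named. Single list members given for IMQ-treated skin by diet, beyond these, were chosen after their values were seen.

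The IMQ response score used genes called for the IMQ effect averaged over both diets with an absolute log2 change of at least 1, a choice that is orthogonal to the interaction. Diet labels were permuted within treatments over all 252 rearrangements, or 63504 for the difference of both treatments, in two-sided exact tests. For that difference this tests for no diet effect in either treatment, not for no interaction alone.

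On simulated data with 22180 genes, 200 of them changed, 36% of changes of log2 0.5, 94% of log2 1 and 100% of log2 2 were recovered for IMQ in CD-fed mice, and 18%, 80% and 100% for the interaction. Between 4 and 12 false calls were made per contrast. With 1 list shifted, that list was called upward and 0 unshifted lists were called. Each simulated gene varied independently of the others and equally in all groups. False calls from correlated genes or outlying arrays could therefore not be seen.

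Alternatives were a further quantile normalization, centring of each array on its median, a filter at the 40th percentile of mean signal, the mean of all features of a gene, all array features, a trended and robust variance, array weights, only the groups compared, the replicate number as a block, an absolute log2 change of at least 1, other gene choices for the score, and omission of each array in turn. After seeing the data 1 alternative was added, leaving out CD-vehicle 3, HFD-vehicle 3 and HFD-IMQ 4, which lay farthest from the rest of their groups. In all, 5 regrouping tests and 8 tests of explanations were run. Features without a single gene symbol were left out of the main tests and were tested as all array features.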

Results

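Gene expression was measured in abdominal skin of 20 C57/B6 mice at 9 weeks of age, 1 array per mouse. The mice ate control chow (CD) or a high fat diet (HFD), and their shaved abdomen received 62.5 mg of 5% imiquimod cream (IMQ) or vehicle daily for 5 days, with skin taken 24 h after the last application. Imiquimod activates Toll-like receptor 7, and repeated application of the cream gives a widely used mouse model of psoriasis-like skin inflammation. The 4 groups, CD-vehicle, CD-IMQ, HFD-vehicle and HFD-IMQ, held 5 mice each. Each array gave 41345 log2 values, of which 22180 genes entered the tests. Array medians lay between 2.86 and 3.04 and the highest values between 12.9 and 13.1. A group mean at or below these medians is near background, so the size of a change from or to it is uncertain. Of the genes called below this holds in at least 1 group for Birc5, Ccl3, Cd79b, Clec4d, Clec4e, Csta3, Defb3, Dsg4, Krt26, Krt71, Krt72, Krt75, Krtap4-2, Lce3f, Prr9, Serpinb3a, Sprr2d, Sprr2e, Stfa2l1, Tchh, Tchhl1 and Tyr. The number of arrays limits the precision, and the median standard error of a log2 change between 2 groups was 0.136. In a principal component analysis over genes, the first component held 27.2% and the second 16.9% of the variance. HFD-vehicle 3 held 42.8% of the squared distances of its group's arrays from their mean over all genes, HFD-IMQ 4 held 30.0% and CD-vehicle 3 held 28.4%.

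The first comparison asked what the cream changed in skin of chow-fed mice. Keratins of wounded and hyperproliferative epidermis rose: Krt16 went from a mean log2 value of 3.46 ± 1.33 (SD, n = 5) in CD-vehicle to 9.12 ± 0.33 in CD-IMQ, a 50.6-fold difference, and Krt6b rose 75.8-fold (log2 6.24 ± 0.49, SE). S100a8 and S100a9, which together form the neutrophil and keratinocyte alarmin calprotectin, rose 70-fold (6.13 ± 0.37) and 47.3-fold (5.56 ± 0.29). Immediate-early genes, which respond within minutes to growth factors and stress, were lower after the cream: Ccn1 was 11.5-fold lower (-3.52 ± 0.30), Egr1 9.94-fold lower (-3.31 ± 0.35) and Fos 9.01-fold lower (-3.17 ± 0.41). The adipocyte hormone Lep fell 5.51-fold (-2.46 ± 0.45, limma adjusted p = 0.000892).

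By limma, 2424 genes passed in CD-fed mice, 868 higher and 1556 lower in CD-IMQ. The other genes with the largest rises and non-overlapping groups were Csta3 (log2 6.66 ± 0.39), Saa3 (6.05 ± 0.34), an acute-phase protein, Serpinb3a (5.90 ± 0.43), Rptn (5.83 ± 0.29), which encodes the cornified envelope protein repetin, and Sprr2d (5.73 ± 0.42). In CD-vehicle the means of Csta3, Serpinb3a (2.28) and Sprr2d (1.97) lay below the array medians, so the sizes of their rises rest on a baseline near background and are uncertain. Those with the largest falls, besides Ccn1, Egr1 and Fos, were the epidermal keratin gene Krt77 (-4.03 ± 0.39), the natriuretic peptide receptor gene Npr3 (-2.92 ± 0.53), Dusp1 (-2.88 ± 0.30), Nr4a1 (-2.71 ± 0.39) and Serpina3b (-2.70 ± 0.36). In 1971 genes the 5 values of one group all lay above the 5 of the other, where chance gives 0.794% of 22180 genes. The balance of directions depended on scaling and size: 1108 genes were higher and 1301 lower after another quantile normalization, 750 and 1645 after centring of the arrays, and 208 and 155 at an absolute log2 change of at least 1.

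Epidermal and antimicrobial lists rose as groups in CD-fed mice. Of 18 measured SPRR and LCE3 genes, which encode cornified envelope proteins, 15 rose and 0 fell, both over all genes and adjusted over the list alone, among them Sprr1b (log2 4.19 ± 0.21), Sprr2e (4.18 ± 0.29) and Lce3f (4.12 ± 0.26). The last 2 started below the array medians, at 2.45 and 1.47 in CD-vehicle, so the sizes of their rises are uncertain too. Fry gave an adjusted p of 1.63e-09, and the adjusted p with an estimated correlation was 0.000653. Of 24 antimicrobial proteins and alarmins 14 rose and 1 fell, with the same numbers adjusted over the list alone (fry adjusted p = 1.63e-09; adjusted p = 0.000653 with an estimated correlation). They included Lcn2 (2.61 ± 0.18), an iron-binding siderophore trap, and the beta-defensin genes Defb3 (3.30 ± 0.40, from a CD-vehicle mean of 1.83 below the array medians) and Defb4 (2.40 ± 0.32). Of 19 wound keratins and serpins 13 rose and 1 fell, or 15 and 2 adjusted over the list alone (fry adjusted p = 2.25e-09; adjusted p = 0.000653 with an estimated correlation), among them Krt6a (4.36 ± 0.39) and the stefin gene Stfa1 (4.57 ± 0.37). In the terminal differentiation and barrier list 26 of 35 genes rose and 2 fell, or 28 and 2 adjusted over the list alone, including Casp14 (2.97 ± 0.32), Lce1f (2.16 ± 0.26) and Krt1 (2.08 ± 0.24). The list passed fry (adjusted p = 7.38e-05) and not with an estimated correlation (adjusted p = 0.0695 with an estimated correlation).

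Among the cytokines of the IL-23/IL-17 axis and the IL-36 family, 6 of 24 genes rose and 0 fell, or 7 and 0 adjusted over the list alone (fry adjusted p = 0.00014; adjusted p = 0.0965 with an estimated correlation). The members that rose most belonged to the IL-36 family: Il1f6 (IL-36 alpha) by log2 3.98 ± 0.35, Il1f8 (IL-36 beta) by 3.07 ± 0.35, Il1f9 (IL-36 gamma) by 2.81 ± 0.22 and the receptor antagonist gene Il1f5 by 2.52 ± 0.25. Il17f rose 1.65-fold (0.72 ± 0.13, adjusted p = 0.00105). The values of Il17a (0.35 ± 0.17, adjusted p = 0.23), Il22 (-0.23 ± 0.12), Il23a (0.00094 ± 0.12), Cxcl2 (-0.072 ± 0.36) and Reg3g (0.12 ± 0.16) did not pass.

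Among leukocyte lists in CD-fed mice, those of neutrophils and B cells passed. Of 18 neutrophil genes 5 rose and 1 fell, or 10 and 1 adjusted over the list alone (fry adjusted p = 0.00014; adjusted p = 0.0695 with an estimated correlation), with Stfa2l1 up by log2 3.91 ± 0.28 from a CD-vehicle mean of 2.59, below the array medians, the granulocyte colony stimulating factor receptor gene Csf3r at 1.11 ± 0.18 and Cxcr2 at 0.94 ± 0.18. Without CD-IMQ 1, 9 neutrophil genes rose. Of 19 macrophage and monocyte genes 6 rose and 0 fell, or 8 and 0 adjusted over the list alone, among them Adgre1 (1.12 ± 0.18) and Cd68 (0.88 ± 0.18), and the list did not pass (fry adjusted p = 0.0675). The B cell list passed with 1 of 13 genes risen, also 1 adjusted over the list alone (fry adjusted p = 0.0281; adjusted p = 0.335 with an estimated correlation). It no longer passed without CD-vehicle 4 (adjusted p = 0.0503), CD-vehicle 5 (0.0591), CD-IMQ 4 (0.0718) or CD-IMQ 5 (0.0955). In the T and NK cell list 1 of 15 genes rose, Cd4 (0.70 ± 0.14), also 1 adjusted over the list alone (fry adjusted p = 0.405). The Langerhans and dendritic cell list had 1 risen and 2 fallen genes of 16, or 2 and 2 adjusted over the list alone, with Mgl2, a lectin gene of dermal dendritic cells and macrophages, 3.94-fold lower (-1.98 ± 0.23). Its median was 0.017, its mean -0.077 and its test pointed down (fry adjusted p = 0.595). None of 14 mast cell genes passed, over all genes or adjusted over the list alone (fry adjusted p = 0.482).

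Chemokine and interferon lists did not pass in CD-fed mice. Of 18 chemokines 3 rose and 3 fell, or 3 and 5 adjusted over the list alone, with the platelet chemokine Ppbp up (log2 1.39 ± 0.31) and the eosinophil attractant Ccl24 down (-1.63 ± 0.25). The list median was 0.061, the mean -0.051 and the test pointed down (fry adjusted p = 0.79). Of 26 type I interferon response genes 3 fell and 0 rose, or 5 and 2 adjusted over the list alone, including Ifit2 (-0.66 ± 0.15; fry adjusted p = 0.562), and without CD-IMQ 4 only 1 fell. In the interferon gamma and antigen presentation list 2 of 23 genes fell, also 2 adjusted over the list alone, and both encode class II chains, H2-Aa (-0.54 ± 0.13) and H2-Ab1 (-0.50 ± 0.12). The median was 0.014, the mean -0.078 and the test pointed down (fry adjusted p = 0.688). Of 16 lipid-associated macrophage genes 4 rose, or 4 risen and 1 fallen adjusted over the list alone, led by Fabp5 (1.56 ± 0.19), which keratinocytes also express. The median was -0.18 and the mean -0.036 while the test pointed up (fry adjusted p = 0.743). That count was 2 without CD-vehicle 1 or CD-vehicle 5.

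Immediate-early genes fell as a group in CD-fed mice, 12 of 19 lower and 1 higher, with the same numbers adjusted over the list alone (fry adjusted p = 0.00014; adjusted p = 0.077 with an estimated correlation). Of 23 fibroblast and matrix genes 10 fell and 2 rose, or 14 and 2 adjusted over the list alone, and the list did not pass (fry adjusted p = 0.0595). Tnc (log2 2.23 ± 0.23), a wound matrix glycoprotein, and Timp1 (1.39 ± 0.18) were the risen members, and Fn1 was lower (-0.92 ± 0.19). Without CD-vehicle 1 or CD-IMQ 3 only 5 matrix genes fell, and without CD-IMQ 4 only 6. The adipocyte list had 4 fallen genes of 25, or 7 adjusted over the list alone (fry adjusted p = 0.193), Plin4 among them (-1.31 ± 0.32). 9 fell without CD-IMQ 2 and 7 without HFD-IMQ 4, while Adipoq (-0.47 ± 0.33) did not pass. Of 33 hair shaft and inner root sheath genes 5 fell, also 5 adjusted over the list alone (fry adjusted p = 0.638), including Tchh (-3.31 ± 0.84, to a CD-IMQ mean of 2.75 below the array medians) and Krt25 (-2.28 ± 0.55), both of the inner root sheath. The hair count was 3 without CD-vehicle 1, CD-vehicle 2 or CD-IMQ 2 and 8 without HFD-vehicle 3. In the bulge stem cell list 3 of 12 genes fell, also 3 adjusted over the list alone (fry adjusted p = 0.0595), Cd34 (-1.07 ± 0.17) and Postn (-0.65 ± 0.14) among them.

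Across the remaining lists in CD-fed mice few genes passed. Of 34 cell cycle genes 7 rose and 0 fell, or 11 and 0 adjusted over the list alone (fry adjusted p = 0.0595, and below 0.05 without CD-vehicle 1, CD-vehicle 2 or CD-IMQ 2), including Ccnb2 (log2 0.95 ± 0.19), Birc5 (0.92 ± 0.16) and Plk1 (0.80 ± 0.15). Of 9 basal keratinocyte genes 1 rose and 2 fell, or 2 and 2 adjusted over the list alone (fry adjusted p = 0.688), with Krt14 higher (1.95 ± 0.23) and Dst (-1.06 ± 0.13) and Krt15 (-1.01 ± 0.24) lower. In the sebaceous gland list 3 of 19 genes rose and 1 fell, with the same numbers adjusted over the list alone (fry adjusted p = 0.688): Gsdmc (3.33 ± 0.41) rose and Scd3 (-2.16 ± 0.34), a stearoyl-CoA desaturase gene, fell. Of 22 endothelial genes 2 rose and 2 fell, also 2 and 2 adjusted over the list alone, with Vcam1 higher (0.76 ± 0.17) and Vegfa lower (-1.25 ± 0.22). The median was 0.0055, the mean -0.032 and the test pointed down (fry adjusted p = 0.777). The mammary epithelium list passed with 3 of 15 genes risen, or 4 risen and 1 fallen adjusted over the list alone (fry adjusted p = 0.00393; adjusted p = 0.257 with an estimated correlation), but its median change was 0.098 and only 1 gene rose without CD-vehicle 1, CD-IMQ 3 or CD-IMQ 5. Wnt4 (0.83 ± 0.17) was among the 3. The mammary list averaged 2.80 in CD-vehicle and 2.92 in CD-IMQ, near the array medians and so near background. Of 23 skeletal muscle genes 3 fell, also 3 adjusted over the list alone (fry adjusted p = 0.383), and only 1 without CD-vehicle 1, CD-vehicle 5 or CD-IMQ 5. One gene passed in the fatty acid synthesis list of 21 (fry adjusted p = 0.595) and 1 in the cholesterol synthesis list of 17 (fry adjusted p = 0.525), and 0 in either list adjusted over the list alone. No gene passed in the fatty acid oxidation list of 20 (fry adjusted p = 0.958), the melanocyte list of 11 (0.638) or the red blood cell list of 2 (0.193), over all genes or adjusted over the list alone.

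**Figure D1:**
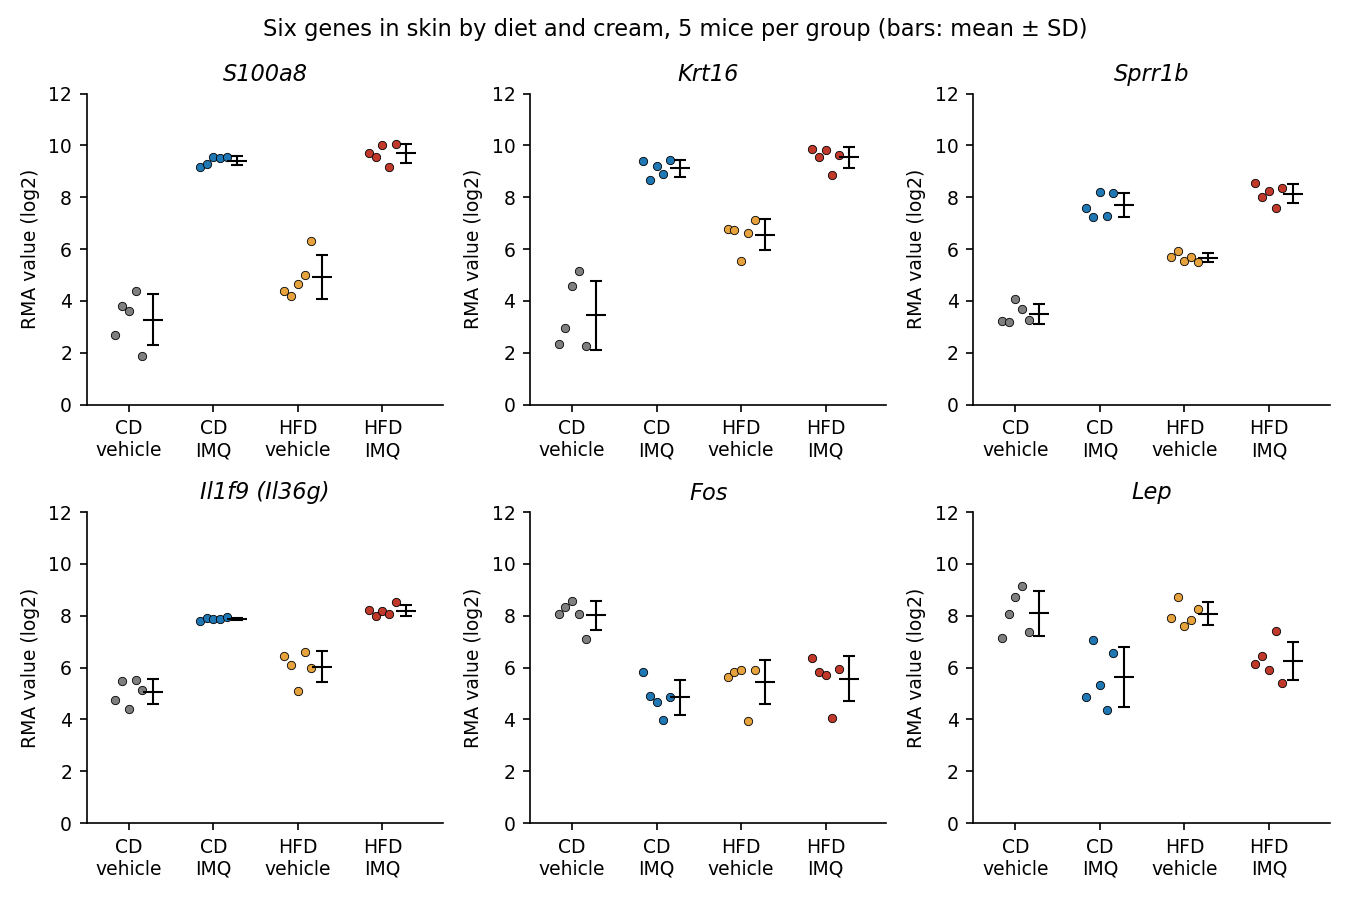
Log2 values of S100a8, Krt16, Sprr1b, Il1f9, Fos and Lep on each of the 20 arrays by group, with bars for the mean and SD of 5 mice. Krt16 averages 3.46 in CD-vehicle, 6.55 in HFD-vehicle, 9.12 in CD-IMQ and 9.54 in HFD-IMQ, and Fos averages 8.02 in CD-vehicle and 5.44 in HFD-vehicle.

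The second comparison asked the same of HFD-fed mice. Hair genes fell: the inner root sheath gene Tchh went from a mean log2 value of 9.95 in HFD-vehicle to 3.02 in HFD-IMQ and Krt71 from 9.66 to 2.87. The HFD-IMQ means lie near the array medians, so the size of these falls is uncertain. S100a8 went from 4.91 ± 0.84 (SD, n = 5) to 9.70 ± 0.36 and S100a9 from 5.10 ± 0.80 to 9.86 ± 0.31, 27.5-fold and 27.2-fold higher. Saa3 rose 34.6-fold (5.11 ± 0.34) and Krt16 rose 7.93-fold (2.99 ± 0.42). Lep was 3.53-fold lower (-1.82 ± 0.45, limma adjusted p = 0.0151), a call that ended without HFD-vehicle 2 or HFD-IMQ 5 (highest adjusted p = 0.0546).

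By limma 1306 genes passed in HFD-fed mice, 809 higher and 497 lower in HFD-IMQ. The other largest rises with non-overlapping groups were those of Csta3 (log2 5.06 ± 0.39), Sprr2e (4.46 ± 0.29), Defb3 (4.27 ± 0.40), Sprr2b (4.11 ± 0.34) and Sprr2d (3.99 ± 0.42). Defb3 averaged 1.75 in HFD-vehicle, below the array medians, so the size and rank of its rise are uncertain. The other largest falls were those of Krt25 (-5.82 ± 0.55), Krt27 (-5.40 ± 0.53), Krt73 (-5.13 ± 0.49), Krt28 (-4.68 ± 0.47), the hair keratin-associated protein gene Krtap4-2 (-4.76 ± 0.74) and the defensin gene Defb8 (-4.88 ± 1.04). Krtap4-2 fell to a mean of 1.86, also below the array medians. In 1344 genes the groups did not overlap, where chance gives 0.794%.

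Of 33 hair shaft and inner root sheath genes 20 fell and 0 rose in HFD-fed mice, or 29 and 1 adjusted over the list alone (fry adjusted p = 0.000906; adjusted p = 0.0457 with an estimated correlation). The list mean went from 5.60 ± 1.44 (SD, n = 5) in HFD-vehicle, where the arrays ranged from 4.54 to 8.09, to 3.05 ± 0.30 in HFD-IMQ. Bulge stem cell genes fell with it, 9 of 12 lower and 1 higher, with the same numbers adjusted over the list alone (fry adjusted p = 5.71e-06; adjusted p = 0.00214 with an estimated correlation), among them the companion layer keratin Krt75 (-3.35 ± 0.47) and Postn (-0.76 ± 0.14). 5 fell without HFD-IMQ 1. Of 11 melanocyte genes 5 fell, or 6 adjusted over the list alone (fry adjusted p = 0.0122; adjusted p = 0.121 with an estimated correlation), including the pigment enzyme genes Tyrp1 (-2.40 ± 0.34), Dct (-2.29 ± 0.35) and Tyr (-1.13 ± 0.23).

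Epidermal and antimicrobial lists rose in HFD-fed mice too. Of 18 SPRR and LCE3 genes 14 rose and 0 fell, or 15 and 2 adjusted over the list alone (fry adjusted p = 7.15e-09; adjusted p = 0.000892 with an estimated correlation). Of 24 antimicrobial genes 11 rose and 1 fell, or 13 and 1 adjusted over the list alone (fry adjusted p = 8.82e-08; adjusted p = 0.00153 with an estimated correlation), with Lcn2 up by log2 1.83 ± 0.18 and Defb4 by 2.52 ± 0.32. Of 19 wound keratins and serpins 14 rose and 0 fell, or 14 and 1 adjusted over the list alone (fry adjusted p = 1.26e-06; adjusted p = 0.00153 with an estimated correlation), Krt6b among them (3.98 ± 0.49). In the IL-23/IL-17 and IL-36 list 7 of 24 genes rose, or 8 adjusted over the list alone (fry adjusted p = 0.00275; adjusted p = 0.113 with an estimated correlation): Il1f6 (2.17 ± 0.35), Il1f9 (2.15 ± 0.22), Il1f8 (1.69 ± 0.35) and Il1b (2.16 ± 0.43) led them. Il17a (0.12 ± 0.17), Il17f (0.29 ± 0.13, adjusted p = 0.262), Il22 (0.088 ± 0.12), Il23a (0.053 ± 0.12), Cxcl2 (0.90 ± 0.36), Reg3g (0.14 ± 0.16) and Adipoq (-0.070 ± 0.33) did not pass. The terminal differentiation list had 8 risen and 3 fallen genes of 35, or 14 and 4 adjusted over the list alone, and did not pass (fry adjusted p = 0.0539), with Rptn higher (2.89 ± 0.29) and Flg2 lower (-1.82 ± 0.33).

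Neutrophil and macrophage genes rose in HFD-fed mice. Of 18 neutrophil genes 9 rose and 1 fell, with the same numbers adjusted over the list alone (fry adjusted p = 5.71e-06; adjusted p = 0.00784 with an estimated correlation): Stfa2l1 rose 12.5-fold (log2 3.65 ± 0.28), and the C-type lectin receptor genes Clec4d and Clec4e rose by 1.70 ± 0.23 and 1.54 ± 0.19, from HFD-vehicle means of 2.91 and 1.99 near or below the array medians. Of 19 macrophage and monocyte genes 12 rose, or 13 adjusted over the list alone (fry adjusted p = 0.00122; adjusted p = 0.0655 with an estimated correlation), led by Adgre1 (1.92 ± 0.18) and Itgam (1.33 ± 0.19). Only 6 rose without HFD-IMQ 1. Tlr7, the receptor that imiquimod activates, rose by 0.85 ± 0.17. The B cell list passed with 2 of 13 genes risen, or 4 adjusted over the list alone (fry adjusted p = 0.0163; adjusted p = 0.206 with an estimated correlation), Cd79b (0.66 ± 0.15) among them. It did not pass without HFD-IMQ 5 (adjusted p = 0.0556). Of 22 endothelial genes 2 rose, Vcam1 (1.12 ± 0.17) and Emcn (0.87 ± 0.16), or 6 adjusted over the list alone (fry adjusted p = 0.0163; adjusted p = 0.17 with an estimated correlation), and 5 rose without HFD-IMQ 4. The red blood cell list passed on its 2 measured genes, 0 called over all genes and 2 adjusted over the list alone (fry adjusted p = 0.0163; adjusted p = 0.164 with an estimated correlation).

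The lipid synthesis and sebaceous gland lists did not pass in HFD-fed mice. Of 21 fatty acid synthesis genes 4 fell, also 4 adjusted over the list alone (fry adjusted p = 0.39), with the elongase and desaturase genes Elovl5 (log2 -1.23 ± 0.18), Elovl6 (-1.14 ± 0.24) and Fads2 (-1.11 ± 0.17) among them. In the sebaceous gland list 5 of 19 genes fell and 1 rose, or 7 and 1 adjusted over the list alone (fry adjusted p = 0.0721): Scd3 (-2.64 ± 0.34), Mc5r (-1.58 ± 0.25) and Fa2h (-1.48 ± 0.32) fell and Gsdmc (2.05 ± 0.41) rose. In that list 3 fell without HFD-vehicle 1 or HFD-IMQ 3. In the immediate-early list 0 of 19 genes passed, over all genes or adjusted over the list alone. The median change was 0.066 and the mean 0.016 while the test pointed down (fry adjusted p = 0.994).

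The responses in the 2 diets overlapped. Of the 868 genes that rose in CD-fed mice 339 also rose in HFD-fed mice, where 31.7 were expected by chance, and of the 1556 that fell 192 also fell, where 34.9 were expected. Of these genes 2 that rose and 6 that fell in CD-fed mice were called the opposite way in HFD-fed mice. Across the 22180 genes, which are not independent replicates, the log2 changes of the 2 diets, which share no arrays, had a Pearson r of 0.493 and a Spearman rho of 0.217.

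**Figure D2:**
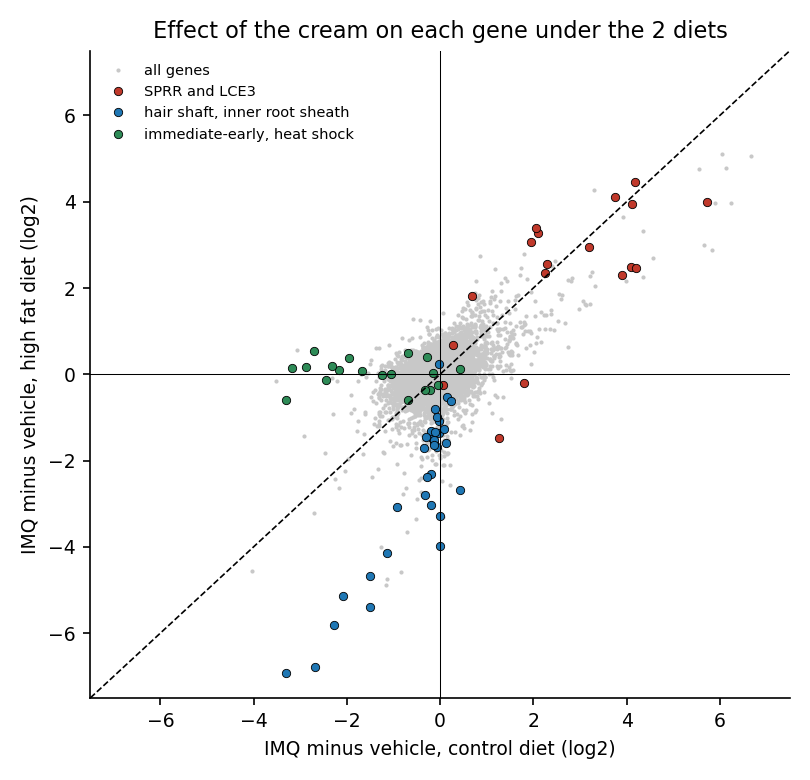
Log2 change with IMQ in CD-fed mice (x axis) against that in HFD-fed mice (y axis) for 22180 genes, with SPRR and LCE3, hair shaft and immediate-early genes coloured. Most SPRR and LCE3 genes, though not all, lie high on both axes. Immediate-early genes have a median of -1.24 on the x axis against 0.066 on the y axis. Hair shaft genes have a median of -1.68 on the y axis.

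The third comparison asked what the diet changed in skin that received vehicle. Hair keratin genes were higher on the high fat diet: Krt71 was 20.2-fold (log2 4.34 ± 0.75) and Krt27 15.4-fold (3.94 ± 0.53) above CD-vehicle. Krt16 averaged 6.55 ± 0.60 (SD, n = 5) in HFD-vehicle against 3.46 ± 1.33 in CD-vehicle, an 8.54-fold difference, and Sprr1b was 4.52-fold higher (2.18 ± 0.21). Immediate-early genes were lower: Nr4a1 was 9.41-fold (-3.23 ± 0.39), Ccn1 7.94-fold (-2.99 ± 0.30) and Fos 5.97-fold (-2.58 ± 0.41) below CD-vehicle. The adipocyte genes Lep (-0.023 ± 0.45, limma adjusted p = 0.99) and Adipoq (-0.19 ± 0.33) did not pass.

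By limma 483 genes passed between the diets in vehicle-treated skin, 271 higher and 212 lower in HFD-vehicle. The balance of directions depended on the setting: 219 were higher and 233 lower after centring of the arrays, and 38.7% were higher when only the groups compared entered the fit. The other largest rises with non-overlapping groups were those of Krtap4-2 (log2 4.18 ± 0.74), Prr9 (3.93 ± 0.54), Tchh (3.89 ± 0.84), Krt72 (3.85 ± 0.53), Krt25 (3.48 ± 0.55) and Tchhl1 (3.45 ± 0.59). In CD-vehicle Krtap4-2 (2.44) and Tchhl1 (2.28) averaged below the array medians and Krt72 (2.93) among them, so the sizes and ranks of these 3 are uncertain. The calls of Tchh and Tchhl1 ended when only the groups compared entered the fit (highest adjusted p = 0.0697 and 0.0547). That of Tchh also ended with a trended, robust variance. The other largest falls were those of Dusp1 (-2.54 ± 0.30), Atf3 (-2.44 ± 0.32), Egr1 (-2.34 ± 0.35), Zfp36 (-2.24 ± 0.27) and Fosb (-2.22 ± 0.24), all immediate-early genes. In 874 genes the groups did not overlap, where chance gives 0.794%. The count of called genes was 231 without CD-vehicle 3, 312 without CD-vehicle 5, 260 without HFD-vehicle 1 and 305 without HFD-vehicle 3. It was 137 when only the groups compared entered the fit. Over all array features 316 features passed, which is not a count of genes.

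Of 33 hair shaft and inner root sheath genes 19 rose and 0 fell on the high fat diet, or 29 and 0 adjusted over the list alone (fry adjusted p = 0.00656; adjusted p = 0.0734 with an estimated correlation). The list mean was 5.60 ± 1.44 (SD, n = 5) in HFD-vehicle, with HFD-vehicle 3 highest at 8.09, against 3.56 ± 0.39 in CD-vehicle. On omission of single arrays 13 to 20 of these genes rose and 0 fell. Without HFD-vehicle 3, 20 genes rose and the median change was 0.90 in place of 1.70. Melanocyte genes moved with them: 3 of 11 rose, or 4 adjusted over the list alone (fry adjusted p = 0.0273; adjusted p = 0.127 with an estimated correlation), Tyrp1 among them (log2 1.93 ± 0.34). That list no longer passed without CD-vehicle 3 (adjusted p = 0.0554), CD-vehicle 4 (0.0585) or CD-vehicle 5 (0.0584), and 1 gene rose without CD-vehicle 3 or CD-vehicle 5. The bulge list passed with 1 of 12 genes risen, Krt75 (2.63 ± 0.47), or 2 adjusted over the list alone (fry adjusted p = 0.0219; adjusted p = 0.127 with an estimated correlation), and not without CD-vehicle 3 (adjusted p = 0.0554).

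Wound keratin, SPRR, terminal differentiation and antimicrobial lists were higher in HFD-vehicle than in CD-vehicle skin. Whether the diet gave this, or material of IMQ-treated mice in these samples, was not settled. Of 19 wound keratins and serpins 11 rose and 1 fell, or 14 and 2 adjusted over the list alone (fry adjusted p = 0.000463; adjusted p = 0.0253 with an estimated correlation). Besides Krt16 they included Krt6a (log2 2.65 ± 0.39), Krt6b (2.50 ± 0.49) and Serpinb3a (2.32 ± 0.43). The list mean was 4.62 ± 0.32 (SD, n = 5) in CD-vehicle, 5.66 ± 0.11 in HFD-vehicle, 6.96 ± 0.20 in CD-IMQ and 7.18 ± 0.30 in HFD-IMQ. Of 18 SPRR and LCE3 genes 5 rose, or 8 adjusted over the list alone (fry adjusted p = 0.00656; adjusted p = 0.0839 with an estimated correlation), with Sprr1a (2.31 ± 0.39) and Lce3d (1.92 ± 0.27) among them. In the terminal differentiation list 11 of 35 rose, or 19 adjusted over the list alone (fry adjusted p = 0.0219; adjusted p = 0.127 with an estimated correlation), led by Rptn (2.83 ± 0.29). That list no longer passed without CD-vehicle 3 (adjusted p = 0.0503), and 7 of its genes rose without CD-vehicle 1, 3 or 5 or HFD-vehicle 1 or 4. Of 24 antimicrobial genes 5 rose and 1 fell, or 8 and 2 adjusted over the list alone (fry adjusted p = 0.00656; adjusted p = 0.0734 with an estimated correlation), with Lcn2 higher by 0.98 ± 0.18. In that list 2 genes rose without CD-vehicle 5 and 3 without CD-vehicle 1, CD-vehicle 3, HFD-vehicle 1 or HFD-vehicle 4.

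The calls of Krt6b, Serpinb3a, Sprr1a, Il1f6, Krt75, Tyrp1, Plk1 and Cma1 between the diets in vehicle-treated skin held without any single array and ended when only the groups compared entered the fit (adjusted p = 0.0760, 0.0666, 0.0506, 0.0759, 0.0627, 0.0568, 0.0515 and 0.0602). S100a8 was 3.11-fold higher in HFD-vehicle (log2 1.64 ± 0.37, limma adjusted p = 0.0209), a call that ended without CD-vehicle 1 or CD-vehicle 5 (highest adjusted p over all settings 0.122). S100a9 was 2.21-fold higher (1.14 ± 0.29, adjusted p = 0.0389), and its call ended without CD-vehicle 1, 3 or 5 or HFD-vehicle 1, 4 or 5 (highest 0.144). Il1f9 was 1.97-fold higher (0.98 ± 0.22, adjusted p = 0.0225), and was not called without CD-vehicle 1, CD-vehicle 3, HFD-vehicle 1 or HFD-vehicle 4 (highest 0.127). In the IL-23/IL-17 and IL-36 list 4 of 24 genes rose, or 5 adjusted over the list alone, Il1f6 (1.88 ± 0.35) among them. Only 1 rose without CD-vehicle 3 or HFD-vehicle 1, and 2 without CD-vehicle 1 or HFD-vehicle 4. The list did not pass (fry adjusted p = 0.123) except without HFD-vehicle 3 (adjusted p = 0.0148) or CD-vehicle 2 (0.049). Il17a (0.18 ± 0.17), Il17f (0.21 ± 0.13), Il22 (-0.13 ± 0.12), Il23a (-0.065 ± 0.12), Cxcl2 (-0.54 ± 0.36), Reg3g (0.075 ± 0.16) and Defb4 (0.19 ± 0.32) did not pass.

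Immediate-early genes fell as a group with the diet, 11 of 19 lower, or 14 lower and 1 higher adjusted over the list alone (fry adjusted p = 0.00121; adjusted p = 0.0734 with an estimated correlation). Their list mean was 6.83 ± 0.59 (SD, n = 5) in CD-vehicle, 5.54 ± 0.19 in HFD-vehicle, 5.42 ± 0.16 in CD-IMQ and 5.55 ± 0.28 in HFD-IMQ. Of 34 cell cycle genes 4 rose, or 19 adjusted over the list alone (fry adjusted p = 0.0219; adjusted p = 0.127 with an estimated correlation), with the mitotic kinase gene Plk1 higher by log2 0.77 ± 0.15. The cell cycle list no longer passed without CD-vehicle 3 (adjusted p = 0.0507). 8 of its genes rose without CD-vehicle 1, CD-vehicle 2 or HFD-vehicle 5, and 2 without CD-vehicle 3, CD-vehicle 5, HFD-vehicle 2 or HFD-vehicle 3. Of 14 mast cell genes 2 fell, the chymase gene Cma1 (-0.67 ± 0.14) and the tryptase gene Tpsb2 (-0.75 ± 0.18), or 3 adjusted over the list alone (fry adjusted p = 0.0219; adjusted p = 0.127 with an estimated correlation). The mast cell list did not pass without CD-vehicle 3 (adjusted p = 0.0507) or HFD-vehicle 3 (0.0526). The call of Tpsb2 ended without CD-vehicle 3, CD-vehicle 5, HFD-vehicle 1, HFD-vehicle 2 or HFD-vehicle 3 (highest adjusted p = 0.187). The Langerhans and dendritic cell list passed downward (median -0.18; fry adjusted p = 0.0227; adjusted p = 0.127 with an estimated correlation), though its called gene Epcam was higher (0.85 ± 0.20) and adjusted over the list alone 1 rose and 2 fell. Epcam is also expressed by other epithelial cells, and its own call ended without CD-vehicle 1, CD-vehicle 3, CD-vehicle 5 or HFD-vehicle 3 (highest adjusted p = 0.191). The list did not pass without CD-vehicle 3 (adjusted p = 0.0554), CD-vehicle 4 (0.0581) or HFD-vehicle 3 (0.109). The mammary list passed with 0 of 15 genes called, over all genes or adjusted over the list alone (fry adjusted p = 0.0438; adjusted p = 0.211 with an estimated correlation). Leaving out any of 16 single arrays ended that call. The mammary list averaged 2.90 in HFD-vehicle and 2.80 in CD-vehicle, near background.

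The lipogenic enzyme genes Fasn, which encodes fatty acid synthase, and Acaca, which encodes acetyl-CoA carboxylase, were 3.61-fold (log2 -1.85 ± 0.44, limma adjusted p = 0.0277) and 3.13-fold (-1.64 ± 0.39, adjusted p = 0.0277) lower in HFD-vehicle than in CD-vehicle, with non-overlapping groups. Both calls ended without CD-vehicle 3, 4 or 5 or HFD-vehicle 1, 3 or 4 (highest adjusted p = 0.0853 and 0.0939). Of the 21 genes of their list 4 fell and 0 rose, or 5 and 1 adjusted over the list alone, and the list did not pass (fry adjusted p = 0.182). In it 0 genes fell without CD-vehicle 3, 4 or 5 or HFD-vehicle 1, 3 or 4, and 2 without HFD-vehicle 2 or HFD-vehicle 5. The neutrophil list did not pass either, with 1 of 18 genes lower, also 1 adjusted over the list alone. Its median was 0.022, its mean -0.014 and its test pointed down (fry adjusted p = 1).

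**Figure D3:**
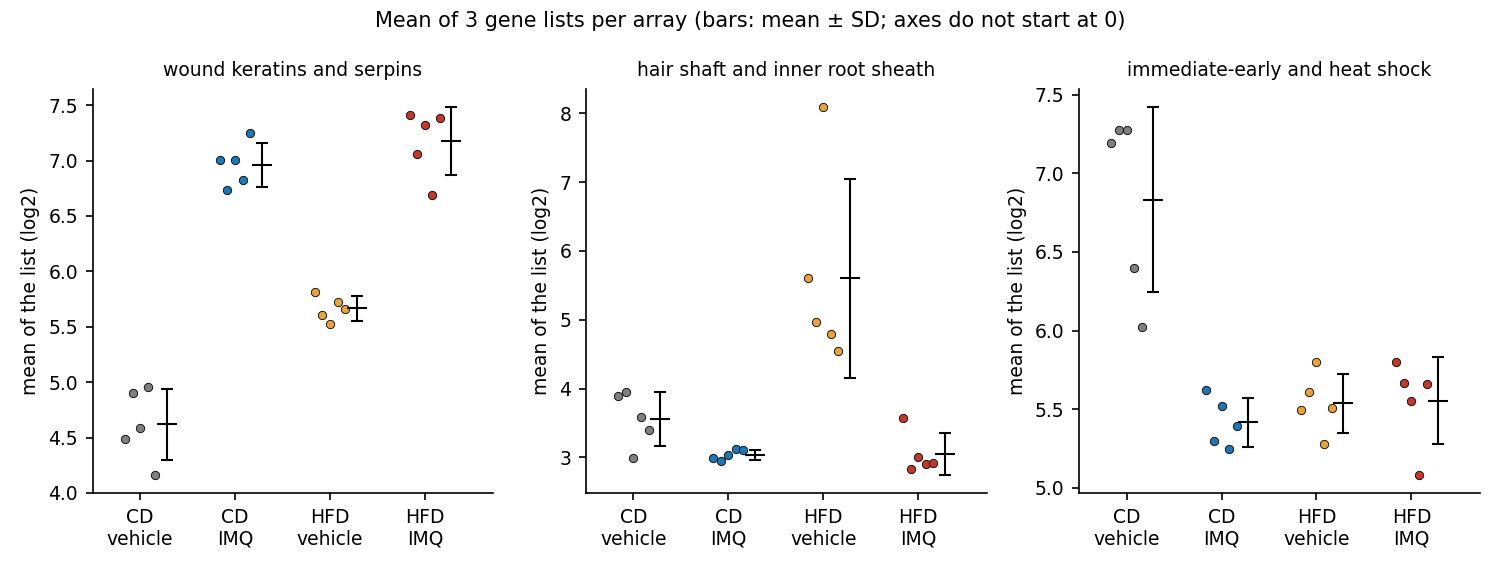
Mean log2 value over the wound keratin, hair shaft and immediate-early lists on each of the 20 arrays by group, with bars for the mean and SD of 5 mice; the axes do not start at 0. The hair shaft list averages 5.60 in HFD-vehicle, with 1 array at 8.09, against 3.56 in CD-vehicle, and the immediate-early list averages 6.83 in CD-vehicle against 5.42 to 5.55 in the other groups.

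The fourth comparison asked how IMQ-treated skin differed between the diets. None of the 22180 genes passed by limma, while 2289 had an unadjusted p below 0.05, where 1109 are expected by chance. The genes with the smallest p, none of which passed, were Usp17ld (log2 -0.83 ± 0.13, n = 5 per group, limma adjusted p = 0.051), the olfactory receptor gene Olfr503 (-1.15 ± 0.20, 0.0702), Pdk4 (1.29 ± 0.23, 0.0827), a kinase gene that restrains glucose oxidation, C1qtnf3 (1.02 ± 0.19, 0.142) and Clec4e (0.99 ± 0.19, 0.161). S100a8 averaged 9.70 ± 0.36 (SD, n = 5) in HFD-IMQ and 9.41 ± 0.18 in CD-IMQ, and Krt16 averaged 9.54 ± 0.39 and 9.12 ± 0.33. The other genes set in advance were not called either, with log2 changes of 0.35 ± 0.29 for S100a9, 0.20 ± 0.18 for Lcn2, 0.31 ± 0.32 for Defb4, 0.53 ± 0.39 for Krt6a, 0.32 ± 0.22 for Il1f9, -0.045 ± 0.17 for Il17a, -0.21 ± 0.13 for Il17f, 0.18 ± 0.12 for Il22, -0.013 ± 0.12 for Il23a, 0.43 ± 0.36 for Cxcl2, 0.092 ± 0.16 for Reg3g, 0.62 ± 0.45 for Lep and 0.21 ± 0.33 for Adipoq.

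None of the 31 lists passed between the diets in IMQ-treated skin, the smallest fry adjusted p being 0.0615 for the mammary list. Adjusted over the list alone, 7 of 21 fatty acid synthesis genes were lower in HFD-IMQ, among them Fasn (log2 -1.53 ± 0.44), Acly (-1.06 ± 0.28) and Scd1 (-0.78 ± 0.26), and 6 of 18 SPRR and LCE3 genes were higher, among them Sprr2g (1.08 ± 0.22) and Sprr2f (0.89 ± 0.19). Likewise adjusted over the list alone, 4 of 22 endothelial genes, 2 of 18 neutrophil genes and 2 of 20 fatty acid oxidation genes were higher, the last being Pdk4 and Angptl4 (1.18 ± 0.30). The single B cell and fibroblast genes that were higher were Cd79b and Lox, and the single mammary gene that was lower was Krt19. In the other 23 lists 0 genes passed on either count. Median, mean and test differed in sign for the T and NK cell list (0.0030, -0.064, down), the hair shaft list (-0.057, 0.0098, down) and the melanocyte list (-0.043, 0.030, up).

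The count of 0 between the diets in IMQ-treated skin depended on single arrays: 20 genes passed without HFD-IMQ 4, 3 without CD-IMQ 2, 2 without CD-vehicle 2, CD-vehicle 5, HFD-vehicle 2 or HFD-vehicle 3, and 1 without CD-vehicle 3, CD-IMQ 4, CD-IMQ 5, HFD-vehicle 5, HFD-IMQ 1, HFD-IMQ 3 or HFD-IMQ 5. Without HFD-IMQ 4 Usp17ld, Olfr503, Pdk4, C1qtnf3 and Clec4e passed, and so did the SPRR and LCE3 list (adjusted p = 0.024), the fatty acid synthesis list (0.024), the endothelial list (0.0484) and the mammary list (0.0484). In 370 genes the groups did not overlap, where chance gives 0.794%. Across genes the diet effects in vehicle-treated and IMQ-treated skin, which share no arrays, had a Pearson r of -0.0957 and a Spearman rho of -0.155.

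The interaction test asked whether the response to the cream differed between the diets. Immediate-early genes gave the largest positive terms, falling with IMQ in CD-fed mice and starting low in HFD-vehicle: Ccn1 averaged 8.67 ± 0.81 (SD, n = 5) in CD-vehicle, 5.15 ± 0.37 in CD-IMQ, 5.68 ± 0.53 in HFD-vehicle and 5.52 ± 0.30 in HFD-IMQ, an interaction of log2 3.36 ± 0.42 (limma adjusted p = 0.00124). Fos (3.31 ± 0.58), Nr4a1 (3.24 ± 0.55), Dusp1 (3.05 ± 0.42), a phosphatase gene that limits MAP kinase signalling, and Egr1 (2.72 ± 0.50) followed. Hair genes gave the largest negative terms: Krt72 averaged 2.93 ± 0.25 in CD-vehicle, 2.93 ± 0.28 in CD-IMQ, 6.78 ± 1.87 in HFD-vehicle and 2.79 ± 0.40 in HFD-IMQ, an interaction of -3.99 ± 0.74 (adjusted p = 0.0131). Outside HFD-vehicle these means lie at or below the array medians, so the size and rank of that term are uncertain. Rptn (-2.94 ± 0.41, adjusted p = 0.00136) rose by 5.83 in CD-fed and by 2.89 in HFD-fed mice.

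By limma 147 genes passed the interaction test, 105 with a positive and 42 with a negative term. After another quantile normalization 99 passed, 58 positive and 41 negative, and after centring of the arrays 166 were positive and 38 negative. Zfp36 (log2 2.51 ± 0.39), Atf3 (2.34 ± 0.45), Ier2 (2.31 ± 0.48), Fosb (2.28 ± 0.34) and Btg2 (2.23 ± 0.42) completed the 10 largest positive terms. The call of Ier2 ended without CD-IMQ 4, CD-IMQ 5, HFD-vehicle 1 or HFD-IMQ 2 (highest adjusted p = 0.0626). Among the 10 largest negative terms were also Krt27 (-3.91 ± 0.76), Prr9 (-3.75 ± 0.77), S100a3 (-2.99 ± 0.59) and the hair desmoglein gene Dsg4 (-2.93 ± 0.60). The calls of Krt27 (highest adjusted p = 0.0549) and S100a3 (0.0526) ended with a trended, robust variance, as did those of Prr9 and Dsg4. The last 2 also ended without HFD-vehicle 1 or HFD-IMQ 2 (highest 0.0677 and 0.0597), and Prr9 also without CD-IMQ 5. Krt28 (-3.17 ± 0.67) lost its call without CD-IMQ 4, CD-IMQ 5, HFD-vehicle 1, HFD-IMQ 2 or HFD-IMQ 5 (highest 0.0734). Krt25 (-3.53 ± 0.78), Krt26 (-3.28 ± 0.73), Krt73 (-3.05 ± 0.69) and Krt16 (-2.67 ± 0.59, adjusted p = 0.0387) lost theirs on omission of any of 11, 12, 13 and 16 single arrays (highest 0.0832, 0.0817, 0.0922 and 0.0806). Krt26 and Dsg4 averaged below the array medians outside HFD-vehicle, so the sizes of their terms are uncertain too.

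The interaction count was 83 without CD-vehicle 3, 57 without CD-IMQ 4, 75 without CD-IMQ 5, 60 without HFD-vehicle 1, 95 without HFD-IMQ 1, 61 without HFD-IMQ 2 and 94 without HFD-IMQ 5. None of the other genes set in advance passed: Krt6a (log2 -2.12 ± 0.54, limma adjusted p = 0.0714), S100a8 (-1.35 ± 0.53, 0.211), S100a9 (-0.80 ± 0.41), Lcn2 (-0.77 ± 0.25), Il1f9 (-0.66 ± 0.32), Il17f (-0.43 ± 0.19, 0.277), Il17a (-0.22 ± 0.24), Il22 (0.31 ± 0.18), Il23a (0.052 ± 0.17), Cxcl2 (0.97 ± 0.50), Reg3g (0.017 ± 0.23), Defb4 (0.12 ± 0.46), Lep (0.64 ± 0.64) and Adipoq (0.40 ± 0.47).

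Of the 31 lists 4 passed the interaction test, each with an adjusted p of 0.19 with an estimated correlation. Immediate-early genes had 9 of 19 positive terms and 0 negative, or 13 and 0 adjusted over the list alone (median log2 1.21; fry adjusted p = 0.0152). Wound keratins and serpins had 2 of 19 negative terms, or 12 negative and 3 positive adjusted over the list alone (median -0.90; fry adjusted p = 0.0299). The wound list no longer passed without CD-vehicle 5 (adjusted p = 0.054), CD-IMQ 1 (0.0556), CD-IMQ 3 (0.0519), CD-IMQ 5 (0.0576), HFD-vehicle 1 (0.05) or HFD-IMQ 2 (0.0517), after centring of the arrays (0.0526) or with the replicate number as a block (0.0714). In it 5 genes were negative without HFD-vehicle 3 and 0 without CD-IMQ 1, 3, 4 or 5, HFD-vehicle 1 or 2, or HFD-IMQ 1, 2, 3 or 4. The bulge list had 1 of 12 negative terms, or 5 adjusted over the list alone (median -0.32; fry adjusted p = 0.0328). Leaving out any of 10 single arrays ended its call. The mammary list had 0 of 15 terms called, or 2 negative adjusted over the list alone (median -0.19; fry adjusted p = 0.0105). Its group means of 2.80 to 2.92 lie near the array medians, so this term is one between values near background. Of 33 hair shaft genes 7 had negative terms, or 20 adjusted over the list alone, and the list did not pass (median -1.62; fry adjusted p = 0.0786) except without HFD-vehicle 3 (adjusted p = 0.00828), HFD-vehicle 4 (0.04) or HFD-vehicle 5 (0.0303). The count of 7 was 3 without CD-IMQ 4, CD-IMQ 5, HFD-vehicle 1, HFD-IMQ 2 or HFD-IMQ 5, 4 without CD-vehicle 5, CD-IMQ 3 or HFD-IMQ 3, and 11 without HFD-vehicle 4. Of 18 SPRR and LCE3 genes 2 had negative terms, or 6 negative and 4 positive adjusted over the list alone (fry adjusted p = 0.558). Median, mean and test differed in sign for the B cell list (-0.044, 0.018, up), the fatty acid synthesis list (0.034, 0.011, down) and the fibroblast list (0.034, -0.014, up), none of which passed.

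An IMQ response score summarised each array as the mean of 185 genes that rose and 106 that fell with IMQ averaged over the diets, the latter with reversed sign. It averaged 0.604 ± 0.118 (SD, n = 5) in CD-vehicle, 2.34 ± 0.119 in CD-IMQ, 0.796 ± 0.227 in HFD-vehicle and 2.56 ± 0.198 in HFD-IMQ. The score was 0.192 higher with HFD in vehicle-treated skin (two-sided exact permutation p = 0.143, adjusted over 3 tests 0.214) and 0.223 higher in IMQ-treated skin (exact p = 0.0794, adjusted 0.214), and these differences differed by 0.0305 (exact p = 0.865, adjusted 0.865). Without HFD-vehicle 3 the vehicle difference was 0.334 (exact p = 0.0159), without HFD-vehicle 4 it was 0.0795 (exact p = 0.548) and without HFD-vehicle 5 it was 0.0519 (exact p = 0.746). Without HFD-IMQ 2 or HFD-IMQ 4 the IMQ difference was 0.274 (exact p = 0.0476) or 0.300 (exact p = 0.0397), while the difference between both treatments ranged from -0.113 to 0.170 on omission of single arrays. A score over all genes called gave 0.0800 in vehicle-treated skin (exact p = 0.0794), -0.0031 in IMQ-treated skin (exact p = 0.921) and -0.0831 between them (exact p = 0.184). Over the 185 genes that rose alone, such as S100a8 and Krt16, the vehicle difference was 0.571 (exact p = 0.00794, the smallest that 252 rearrangements can give), and over the 106 that fell it was -0.468 (exact p = 0.0635). The difference between both treatments was -0.274 over the risen genes (exact p = 0.34) and 0.561 over the fallen ones (exact p = 0.0313). The small value over both sides thus sums estimates of opposite sign, of which that over the risen genes did not pass. The p values by side were not adjusted for the number of scores tried. Shuffling diets within treatments tests for no diet effect in either treatment, so these p values are not for the interaction alone.

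**Figure D4:**
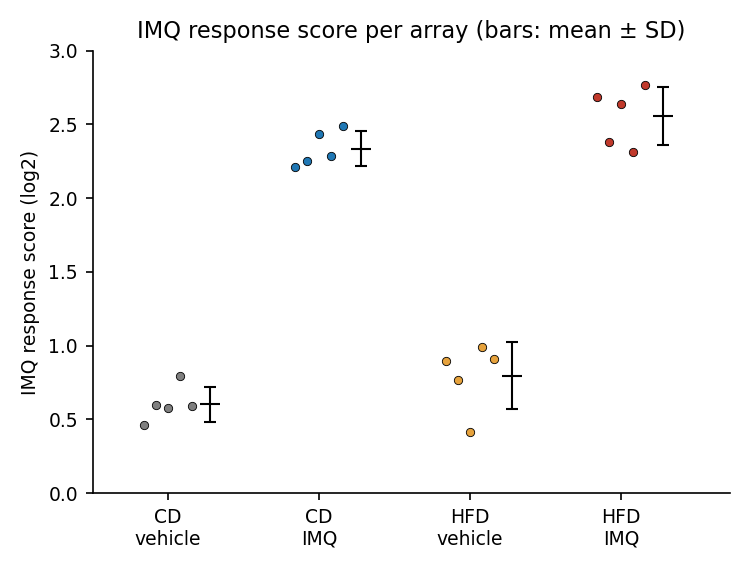
IMQ response score of each of the 20 arrays by group, the mean log2 value of 185 genes that rose with IMQ and of 106 that fell with reversed sign, with bars for the mean and SD of 5 mice. The groups average 0.604 in CD-vehicle, 0.796 in HFD-vehicle, 2.34 in CD-IMQ and 2.56 in HFD-IMQ.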

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

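Of the tests of explanations in this part, only the 5 regroupings and the first, neutrophil-gene test of mixing were fixed before their results were seen; the others, among them the macrophage and antimicrobial gene sets, the single-array tests and the melanocyte test, were chosen only after the result was seen.

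Regrouping the arrays at random tested whether other groupings of the mice give as many called genes, with 100 groupings per comparison, the real one included. For IMQ in CD-fed mice only 1 grouping, the real one, reached 2424 genes, and the highest other gave 285. For IMQ in HFD-fed mice 1 reached 1306 (highest other 12), for HFD in vehicle-treated skin 1 reached 483 (highest other 29) and for the interaction 1 reached 147 (highest other 58). The smallest share that 100 groupings can give is 1 in 100, so chance is unlikely for these counts but not excluded. For the interaction the diets were shuffled within treatments. That tests for no diet effect in either treatment, not for no interaction alone. For HFD in IMQ-treated skin the real limma count was 0, which any grouping reaches, as all 100 did (highest other 5), so this regrouping says nothing about chance; 2289 genes had an unadjusted p below 0.05, where 1109 are expected.

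Wound keratin and SPRR genes such as Krt16 and Sprr1b were higher in HFD-vehicle than in CD-vehicle skin. Chance was tested only for the total of 483 genes called, not for these genes. Without HFD-vehicle 3 the wound keratin list kept a median change of 0.82 and a fry adjusted p of 0.000401. That omission is a weak test, since HFD-vehicle 3 had the lowest wound keratin mean of its group (5.53). On omission of any single array 10 to 12 wound keratin genes rose and 0 to 2 fell, and 5 to 6 SPRR and LCE3 genes rose and 0 fell. These counts therefore do not rest on 1 array. The SPRR and LCE3 list, unlike the wound keratin list, did not pass camera with an estimated correlation. RNA or skin of IMQ-treated mice mixed into these samples could account for the median rise of 27 epidermal genes. The mean share that these genes need was 6.82% (2.56% to 9.18%). The epidermal, neutrophil and antimicrobial sets held only genes called for the average IMQ effect with a log2 rise of at least 1. Sprr1a (9.46 ± 0.89, SD, in HFD-vehicle and 9.27 ± 0.33 in HFD-IMQ) and S100a7a (4.90 ± 1.25 and 4.08 ± 0.47) were outside them. The share was therefore not tested on the rises of these 2 genes. In turn 3 gene sets were tried, each by the median over its genes of observed minus predicted log2 rise. The mean over arrays was -0.257 ± 0.140 (SD over 5 arrays) for 8 neutrophil genes, -0.175 ± 0.286 for 10 macrophage genes and -0.509 ± 0.515 for 9 antimicrobial genes. The summary used matters for the antimicrobial genes: their median rise averaged 0.624 and their median predicted rise 0.525. In the other sets the median rise lay below the predicted one. The neutrophil set met the bound written in advance against mixing, but that bound was too weak because its baseline median of 2.66 lies near the floor and its predicted rise is only 0.170; a rule that a set decides only with a baseline of at least 5 and a predicted rise above the SD was set after these outcomes were seen, no set meets it (the antimicrobial baseline is 3.44 and the macrophage rise 0.0623), and by the looser earlier bound the macrophage and antimicrobial genes had gone with mixing. For the genes in these sets a small admixture therefore cannot be told apart from an effect of the diet on the epidermis, which stays open and untested.

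Immediate-early genes such as Fos and Egr1 were higher in CD-vehicle than in the other 3 groups. Separate lowering of these genes by the diet and by the cream, each by a fixed amount, predicts no interaction, and the list's median interaction was 1.21 (fry adjusted p = 0.0152; adjusted p = 0.19 with an estimated correlation). The value of 0.19 is from camera, which compares the list with other genes, so it does not answer the same question as fry. By limma 9 of the list's 19 genes passed the interaction, which argues against separate fixed lowering on the log2 scale for these genes. The interaction partly restates the pattern itself. Collection or handling of the CD-vehicle mice apart from the others could raise such rapidly induced genes: the SD of their list mean was 2.12 times the largest SD of the other groups, and this handling cannot be told apart from the group itself, because collection order is not given in the sources used here. A floor that both diet and cream reach stays open as a biological explanation and was not tested.

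Hair shaft genes such as Krt71 were higher in HFD-vehicle than in CD-vehicle skin. With all arrays the hair shaft list did not pass camera with an estimated correlation (adjusted p = 0.0734). HFD-vehicle 3 alone does not account for the rise, since without it the list's fry adjusted p was 0.000300 with a median change of 0.90. On omission of any single array 13 to 20 of the list's genes rose. More growing hair follicles in the HFD-vehicle samples may account for it: growing follicles hold pigment cells, and without HFD-vehicle 3 the melanocyte list had a median change of 0.196 (fry adjusted p = 0.0120), the lowest of the 4 remaining array means being 3.93 against 3.86 for the highest CD-vehicle array. With all arrays the melanocyte list did not pass camera with an estimated correlation (adjusted p = 0.127). Its fry call was lost without CD-vehicle 3 (0.0554), CD-vehicle 4 (0.0585) or CD-vehicle 5 (0.0584). The margin between 3.93 and 3.86 is narrow, and hair cycle stage, shaving or the site sampled could each give such a difference without the diet. Whether the diet itself shifts the hair cycle was not tested.

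By the interaction test the change with IMQ differed between the diets for 4 lists and 147 genes, of which 21 are named here. Between the diets 483 genes passed in vehicle-treated skin and 0 in IMQ-treated skin, so these terms can reflect different vehicle baselines. List medians were 1.21 for immediate-early genes, -0.90 for wound keratins, -0.32 for bulge genes and -0.19 for mammary genes, each with an adjusted p of 0.19 with an estimated correlation. The wound list no longer passed without CD-vehicle 5, CD-IMQ 1, 3 or 5, HFD-vehicle 1 or HFD-IMQ 2 (highest adjusted p = 0.0576), and the bulge list on omission of any of 10 single arrays (highest 0.0773). Of the 21 genes 11 passed in every recomputation. Positive gene terms were those of Ccn1 (3.36), Fos (3.31), Nr4a1 (3.24), Dusp1 (3.05), Egr1 (2.72), Zfp36 (2.51), Atf3 (2.34), Ier2 (2.31), Fosb (2.28) and Btg2 (2.23). Negative terms were those of Krt72 (-3.99), Krt27 (-3.91), Prr9 (-3.75), Krt25 (-3.53), Krt26 (-3.28), Krt28 (-3.17), Krt73 (-3.05), S100a3 (-2.99), Rptn (-2.94), Dsg4 (-2.93) and Krt16 (-2.67).

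Single arrays lay apart from their group in 12 of 188 tests of list means and scores, where chance gives about 1 in 20, or 9.4. The gap of the extreme array as a share of its group's range was 0.736 for basal keratinocyte and 0.734 for bulge genes, both low in CD-vehicle 3. In CD-IMQ it was 0.780 for fatty acid oxidation (CD-IMQ 2 high), 0.751 for sebaceous gland (CD-IMQ 5 low) and 0.892 for mammary genes (CD-IMQ 4 high). HFD-vehicle 3 was low for the IL-23/IL-17 list (0.718), chemokines (0.806) and B cell genes (0.837) and high for melanocyte genes (0.856), and HFD-vehicle 1 was high for lipid-associated macrophage (0.719) and muscle genes (0.762). HFD-IMQ 1 was high for hair shaft genes (0.763).

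Among the 17824 array features without a single gene symbol, limma called 662 for IMQ in CD-fed mice, 185 for IMQ in HFD-fed mice, 66 for HFD in vehicle-treated skin, 1 for HFD in IMQ-treated skin and 23 for the interaction.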

How the results depend on the processing

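Of the alternatives below, only the omission of CD-vehicle 3, HFD-vehicle 3 and HFD-IMQ 4 together was chosen after the results were seen. No called result among the named genes, lists and scores reversed; the other genes were not followed one by one. The balance of directions reversed for HFD in vehicle-treated skin, to 219 higher and 233 lower after centring and to 38.7% higher with only the groups compared. It also reversed for IMQ in CD-fed mice, to 208 higher and 155 lower at an absolute log2 change of at least 1, and score differences that were not called changed sign. Where a value moved the cause was not tested except as stated. Named genes kept their side of the threshold in 8699 recomputations, lost a call in 540 and gained one in 33, and lists did so in 3948, 93 and 144. Of 96 named genes called for IMQ in CD-fed mice 75 passed in every recomputation, of 90 for IMQ in HFD-fed mice 74, of 59 for HFD in vehicle-treated skin 21 and of 21 for the interaction 11. Of 37 list results called by fry 11 ended on omission of 1 array and 3 with a replicate block. In camera with an estimated correlation, which compares a list with other genes, 27 of them did not pass. Lists that did not pass with all arrays passed without 1 array or another: cell cycle, fibroblast, bulge, macrophage and red blood cell for IMQ in CD-fed mice; T and NK cell, fibroblast, differentiation, lipid-associated macrophage, mammary, mast cell and sebaceous for IMQ in HFD-fed mice. The same held for the IL-23/IL-17 and interferon gamma lists for HFD in vehicle-treated skin, and for antimicrobial, cell cycle, hair shaft, differentiation and mast cell lists in the interaction.

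Requiring an absolute log2 change of 1, a stricter threshold by construction, left 363 genes for IMQ in CD-fed mice, 355 in HFD-fed mice, 170 for HFD in vehicle-treated skin and 80 for the interaction. Over all array features 316 features, not genes, passed for HFD in vehicle-treated skin, 69 for the interaction and 1 for HFD in IMQ-treated skin. Of these, 66, 23 and 1 carried no single gene symbol. Only the groups compared, with fewer arrays to estimate the spread, gave 137 genes for HFD in vehicle-treated skin. For HFD in IMQ-treated skin, centring of arrays, the filter on dim genes, the mean of features and the trended variance each gave 1 gene, Usp17ld in each. With the 3 farthest arrays left out, 230 genes passed for HFD in vehicle-treated skin and 30 for HFD in IMQ-treated skin, and the IMQ score difference was 0.321 (exact p = 0.0397). On risen genes alone the vehicle score difference was 0.571 (exact p = 0.00794), and on fallen genes alone the difference of both treatments was 0.561 (exact p = 0.0313). On all genes called the score differed by 0.0800 in vehicle-treated skin (exact p = 0.0794), by -0.0031 in IMQ-treated skin (exact p = 0.921) and by -0.0831 between them (exact p = 0.184). The replicate block gave 2247, 1209, 361, 0 and 124 genes in the order of the report.

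Omission of single arrays gave 1741 to 2636 genes for IMQ in CD-fed mice, 990 to 1370 in HFD-fed mice, 231 to 574 for HFD in vehicle-treated skin, 0 to 20 for HFD in IMQ-treated skin (20 without HFD-IMQ 4) and 57 to 198 for the interaction. The score difference ranged from 0.0519 to 0.334 in vehicle-treated skin (0.334 without HFD-vehicle 3, exact p = 0.0159; 0.0519 without HFD-vehicle 5, exact p = 0.746), from 0.184 to 0.300 in IMQ-treated skin and from -0.113 to 0.170 between them. Low signal limits the cytokine results: Il17a, Il22, Il23a and Reg3g averaged 2.55, 1.14, 2.31 and 1.45 in CD-vehicle, where array medians are 2.86 to 3.04.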

Other observations

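No test in this part was chosen after the result was seen, and none tests an explanation. Of 23 skeletal muscle genes in HFD-fed mice 1 rose and 2 fell, or 1 and 5 adjusted over the list alone (fry adjusted p = 0.138), and 4 fell without HFD-IMQ 2 and 0 without HFD-vehicle 1, HFD-IMQ 3 or HFD-IMQ 5. Of 14 mast cell genes 2 rose, Cma1 (log2 0.64 ± 0.14) among them, also 2 adjusted over the list alone (fry adjusted p = 0.0539). The Langerhans and dendritic cell list had 2 risen and 1 fallen gene of 16, with the same numbers adjusted over the list alone (fry adjusted p = 0.606), and Mgl2 was 3.89-fold lower (-1.96 ± 0.23), close to the 3.94-fold of CD-fed mice. Of 23 fibroblast genes 8 fell and 2 rose, or 11 and 3 adjusted over the list alone (fry adjusted p = 0.0516), with Col1a2 (-0.82 ± 0.19) and Mfap5 (-0.77 ± 0.15) lower and Tnc (1.38 ± 0.23) higher; 4 fell without HFD-vehicle 2, HFD-vehicle 5, HFD-IMQ 3, HFD-IMQ 4 or HFD-IMQ 5, and 5 without HFD-vehicle 1 or HFD-vehicle 4.

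Chemokine genes in HFD-fed mice did not move as one: of 18, 3 rose and 1 fell, or 6 and 1 adjusted over the list alone (fry adjusted p = 0.0721). Ccl3 (log2 1.75 ± 0.34) and Cxcl16 (0.99 ± 0.14) rose, and Ccl24 (-1.38 ± 0.25) fell, as in CD-fed mice (-1.63 ± 0.25). In vehicle-treated skin 2 of the 18 were lower with HFD, or 4 adjusted over the list alone (fry adjusted p = 0.0675) and 0 without CD-vehicle 3, with the monocyte attractant Ccl2 1.97-fold lower (-0.98 ± 0.22, limma adjusted p = 0.018), a call that ended without CD-vehicle 3 (highest adjusted p = 0.128). Tnc, the wound matrix gene, was 2.75-fold higher in HFD-vehicle (1.46 ± 0.23), and 1 of 23 fibroblast genes rose there, or 2 adjusted over the list alone (fry adjusted p = 0.317).

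Interferon and cell cycle lists did not pass in HFD-fed mice. The genes called over all genes went the other way than those of CD-fed mice, but they were few. Adjusted over the list alone, interferon genes went both ways, and none of these lists passed the interaction test with all arrays. Of 26 type I interferon response genes 2 rose with IMQ and 0 fell, or 3 and 0 adjusted over the list alone (fry adjusted p = 0.263). Of 23 interferon gamma and antigen presentation genes 1 rose, or 7 risen and 3 fallen adjusted over the list alone (fry adjusted p = 0.147), and 2 rose without CD-vehicle 1, CD-vehicle 4, CD-IMQ 4, HFD-vehicle 1, HFD-IMQ 2 or HFD-IMQ 3. Of 34 cell cycle genes 1 fell and 0 rose, and 0 adjusted over the list alone (fry adjusted p = 0.361). That count was 2 without CD-vehicle 3 and 0 without CD-vehicle 4 or 5, CD-IMQ 1 or 3, HFD-vehicle 2, 3, 4 or 5, or HFD-IMQ 1, 3 or 4. In the interaction 1 cell cycle gene had a negative term, 2 without CD-IMQ 2, or 10 adjusted over the list alone (median -0.49; fry adjusted p = 0.0786), and the list passed without CD-vehicle 2 (adjusted p = 0.0419) or after another quantile normalization (0.0454).

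Of the other lists in HFD-fed mice, 2 of 16 lipid-associated macrophage genes rose and 1 fell, or 4 and 1 adjusted over the list alone (fry adjusted p = 0.113), with 4 risen without HFD-vehicle 3 or HFD-IMQ 4. In the T and NK cell list 1 of 15 rose, also 1 adjusted over the list alone (fry adjusted p = 0.116). Of 9 basal keratinocyte genes 2 rose and 1 fell, or 2 and 2 adjusted over the list alone (fry adjusted p = 0.71). Of 25 adipocyte genes 2 fell, also 2 adjusted over the list alone (fry adjusted p = 0.703), and 1 without HFD-vehicle 2 or HFD-IMQ 5. Of 17 cholesterol synthesis genes 1 fell, or 3 adjusted over the list alone (fry adjusted p = 0.159), and 3 fell without CD-vehicle 3 and 2 without HFD-vehicle 5 or HFD-IMQ 4. In the fatty acid oxidation list 0 of 20 passed on either count (fry adjusted p = 0.263).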
